A study of Danio rerio with 4 samples.

How the data were processed

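RNA was measured by bulk RNA sequencing in zebrafish (Danio rerio) neural crest cells, sorted by fluorescence for the sox10:DsRed reporter from embryos at 20 hours post fertilization (hpf). Per the labels, RNA was extracted from the sorted cells with a kit for small samples and turned into amplified cDNA with the SMARTer kit before library preparation. The 4 samples fell into 2 groups by the genotype in the labels: 2 nr2f mutant samples and 2 wild-type samples. The titles and table columns of the former name both nr2f2 and nr2f5, whereas their genotype field gives nr2f5 as mutant and nr2f2 as unknown. The labels name the 2 samples of each group as biological replicates.

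The authors deposited 1 table of TPM (transcript abundance scaled to the same total in each library), with a row for each of 65905 Ensembl transcripts, a gene ID and a gene name, and a column for each sample. Kallisto and the genome build GRCz11 are named per the submitters' processing notes; the version of kallisto, the annotation release and the other steps were not given in the sources used here. Values were given for 57775 transcripts, and 8130 had empty cells in all 4 columns. Each column summed to 1e+06 over the transcripts with a value, and 0 columns were left without a sample. TPM keeps no read depth, so the depth of the libraries is unknown here, and no counting interval, detection floor or count model was used. A value of 0 is therefore described only as listed at 0.

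Transcript TPM was summed per gene name, or per gene ID where the name was blank, giving 26267 genes from 30628 gene IDs; 3701 names joined 2 or more gene IDs, such as copies of a gene on alternative scaffolds. Summing by name was chosen after the table was seen and before any test. Values were analysed as log2(TPM + 1), so fold changes are on that scale and understate the changes of low genes. Genes with a mean of 1 TPM or more over the 4 samples were tested, 14217 in all, with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend and robust, which used statmod 1.5.0), comparing mutant with wild-type samples without further terms. P-values are two-sided and were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was said to rise or fall at an adjusted p under 0.05. Errors beside log2 fold changes are the moderated standard errors (SE) of limma, with n = 2 samples per group.

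The tests, the 31 gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The lists covered the Nr2f family, early neural crest, cranial ectomesenchyme, ventral arch, dorsal arch, cartilage and bone, mesenchyme and matrix, pigment cells, peripheral neurons and glia, Hox genes, and the retinoic acid, Notch, Bmp, Fgf and Wnt pathways. They also covered DNA replication, mitosis, p53 targets and apoptosis, immediate early and heat shock genes, mitochondrially encoded and ribosomal protein genes. Markers of other cells that a sort could hold formed further lists: otic vesicle, skeletal muscle, central nervous system progenitors, epidermis and periderm, erythroid, endothelial and myeloid cells, pharyngeal endoderm and gut, notochord and floor plate, and hatching gland and yolk syncytium. Lists were tested with camera in limma with a preset correlation of 0.01, which compares a list with the other genes, and p-values were adjusted over the 31 lists. Camera with an estimated correlation and fry, which asks whether a list's genes move one way without comparing them with other genes, were alternatives.

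Named genes were the Nr2f family, the 10 genes with the largest rise and the 10 with the largest fall, and up to 4 members of each list with the smallest p among those that passed over all genes or over the list alone. The largest changes were taken among genes with an adjusted p under 0.05, a mean of 5 TPM or more, a gene symbol that is not a clone name, and both mutant samples on the same side of both wild-type samples. Where no member of a list passed, the 2 with the highest mean were named. Other genes named in the text are said to have been chosen after their values were seen.

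The procedure was tested on simulated data for this comparison, with 14217 genes of which 200 were changed. With the spread of each gene drawn from the fitted prior, 32% of 2-fold and 70% of 4-fold changes were called, and 3.48% of the calls were on unchanged genes. With the spread set to each gene's moderated estimate, the shares were 46% and 89%, and 14.2% of the calls were on unchanged genes; the other way of drawing the spread was added after this value was seen. In both simulations limma without trend and robust called 0 genes.

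The alternatives were other pseudocounts (0.1 and 5 TPM), no filter or a mean of 5 TPM, median-ratio scaling, quantile normalization, rescaling without mitochondrially encoded and ribosomal protein genes, the replicate number as a block, moderation without trend and robust, tests per transcript, a minimum fold change, lists without shared genes, and leaving out each sample in turn. Where a fit left 1 sample in a group, that sample was assumed to vary like the other group. Summing per gene ID was added after the data were seen. Gene order for the check of linked genes came from the RefSeq table of assembly GRCz12tu, which is not the build of the deposited values, so no coordinates are given. By name or, failing that, by gene ID, 84.3% of the tested genes were matched. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.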

Results

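Neural crest cells carrying the sox10:DsRed reporter were compared between nr2f mutant and wild-type zebrafish embryos at 20 hpf, when cranial neural crest cells have moved into the pharyngeal arches and begin to form ectomesenchyme, the source of the facial skeleton. The comparison asks how Nr2f nuclear receptors act on the fate of cranial ectomesenchyme. Each group held 2 biological replicates. The labels list 88 and 35 embryos for the mutant samples and 110 and 120 for the wild-type samples, without tying these to replicate numbers. Abundances are the deposited TPM, whose read depth is unknown. Genes at 1 TPM or more numbered 13412 and 13186 in mutant replicates 1 and 2, and 14519 and 14333 in wild-type replicates 1 and 2. Of the tested genes, 81 and 243 were listed at 0 in mutant replicates 1 and 2, and 60 and 39 in wild-type replicates 1 and 2. Across genes, Pearson's r of log2(TPM + 1) was 0.975 between the mutant replicates, 0.960 between the wild-type replicates, and 0.934 to 0.957 between samples of different groups; genes are not independent replicates.

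The mutated gene nr2f5 (ENSDARG00000033172) fell in the mutant cells. It stood at 46.5 and 47.1 TPM in mutant replicates 1 and 2 against 579 and 559 TPM in the wild-type replicates, a log2 fold change of -3.58 ± 0.12 (limma, SE, n = 2 per group, adjusted p = 1.1e-06). The related receptor gene nr2f1b rose, from 29.2 and 28.0 TPM in wild-type cells to 114 and 87.4 TPM in mutant cells (log2 fold change 1.77 ± 0.19, adjusted p = 0.0018). The gene nr2f2 (ENSDARG00000040926), named with nr2f5 in the titles of the mutant samples but of unknown genotype in their genotype field, stood at 67.2 and 51.7 TPM in mutant and 73.5 and 59.3 TPM in wild-type cells and did not pass the test (log2 fold change -0.16 ± 0.20, adjusted p = 0.67). The other members did not pass either: nr2f1a at 0.22, nr2f6a at -0.16 and nr2f6b at -0.09, and the signs for nr2f2, nr2f6a and nr2f6b were positive under median-ratio scaling. Of the 6 members, 1 rose and 1 fell, over all genes and also adjusted over the list alone. The family as a list did not stand apart from other genes (adjusted p = 0.98). Both calls remained when any 1 sample was left out, but limma without trend and robust called neither nr2f5 (adjusted p = 0.0631) nor nr2f1b (adjusted p = 0.079), and nr2f1b was not called with no filter on low values (adjusted p = 0.085).

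**Figure D1:**
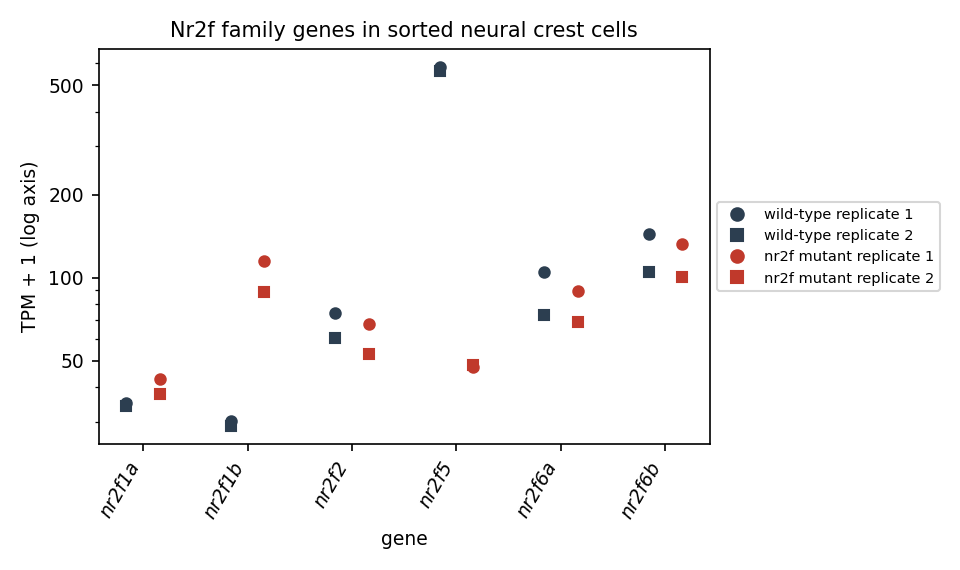
Abundance of the 6 Nr2f family genes in each sample, as TPM + 1 on a log axis, with wild-type samples in dark blue and nr2f mutant samples in red (circles, replicate 1; squares, replicate 2). The mutant samples lie at 46.5 and 47.1 TPM for nr2f5 and the wild-type samples at 579 and 559 TPM, whereas nr2f1b lies higher in both mutant samples.

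Across the transcriptome, 580 of 14217 genes changed, 161 rising and 419 falling in the mutant cells. Of these, 459 changed at least 2-fold, 99 upward and 360 downward. Genes that rose made up 27.8% of the calls. The median log2 fold change of all tested genes was -0.16. Median-ratio scaling brought it to 0.00 and gave 364 rises and 405 falls (47.3% rising), and quantile normalization brought it to 0.03 and gave 235 rises and 254 falls (48.1% rising). Medians of lists are therefore also given relative to the median of all genes. The 2 groups did not overlap for 53.2% of the tested genes, where samples in random order give 33.3% on average. Genes share the same samples, so any difference between samples, of genotype or not, can raise this share. The number of calls was 195 without mutant replicate 1 and 110 without mutant replicate 2, 4 with no filter on low values, and 0 with limma without trend and robust, where 2531 genes had an unadjusted p under 0.05 against 2900 with them. Of the 31 gene lists, 8 passed camera, 3 upward and 5 downward; 0 passed with an estimated correlation or with fry (smallest adjusted p = 0.72 and 0.086), 16 passed without mutant replicate 2 and 13 without wild-type replicate 1.

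The genes with the largest rises were slain1b, sh2d1ab, crygn2, sdhda, scn4bb, cart3, fxyd1, mpdu1b, egr2b and coq9. Their log2 fold changes ran from 3.34 ± 0.40 for slain1b (adjusted p = 0.0027) to 2.09 ± 0.29 for coq9 (adjusted p = 0.0053). Metabolic proteins are encoded by sdhda, coq9 and mpdu1b: sdhda, a subunit of succinate dehydrogenase, rose from 2.38 and 1.27 TPM to 22.3 and 22.8 TPM, and coq9 acts in coenzyme Q synthesis and mpdu1b in protein glycosylation. The hindbrain and glial transcription factor gene egr2b rose from 5.57 and 2.56 TPM to 23.3 and 16.8 TPM (log2 fold change 2.10 ± 0.37, adjusted p = 0.014). The sodium channel subunit gene scn4bb was listed at 0 in wild-type replicate 1 and stood at 1.34 TPM in wild-type replicate 2, against 7.92 and 13.0 TPM in mutant cells. The rises of egr2b and scn4bb were not called without mutant replicate 1 (adjusted p = 0.12 and 0.052) or without mutant replicate 2 (0.092 and 0.15), and those of mpdu1b and coq9 were not called without mutant replicate 2 (0.087 and 0.085).

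The genes with the largest falls were smyhc1, hpdb, prrx1b, tgm2b, eif3eb, nr2f5, fah, npb, hjv and ifitm1. The slow muscle myosin gene smyhc1 fell by 4.56 ± 0.40 on the log2 scale (adjusted p = 8.3e-04), and the ectomesenchyme homeobox gene prrx1b fell from 45.5 and 82.4 TPM to 2.36 and 4.09 TPM (log2 fold change -3.91 ± 0.35, adjusted p = 6.2e-04). Both hpdb and fah, which encode enzymes of tyrosine breakdown, fell. The gene hpdb was listed at 0 in both mutant samples and stood at 22.0 and 12.0 TPM in wild-type cells, and fah fell from 28.8 and 38.2 TPM to 2.3 and 1.55 TPM (log2 fold change -3.56 ± 0.32, adjusted p = 6.2e-04). The neuropeptide gene npb fell from 93.4 and 132 TPM to 8.88 and 10.95 TPM. The interferon-induced gene ifitm1 was listed at 0 in both mutant samples, at 5.09 and 15.7 TPM in wild-type cells, and was not called without mutant replicate 2 (adjusted p = 0.072). The translation factor gene eif3eb fell from 405 and 375 TPM to 28.7 and 28.1 TPM (log2 fold change -3.73 ± 0.14, adjusted p = 1.2e-06). Its value is uncertain, because the fall lay in 1 of 2 gene IDs with that name, and its close paralog eif3ea, chosen after its values were seen, rose from 374 and 386 TPM to 851 and 879 TPM.

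Among genes of cranial ectomesenchyme, 8 fell, 2 rose and 22 of 32 did not pass. The falls were those of prrx1b, twist1a, dlx4b, dlx3b, tbx2b, foxc1b, dlx2a and prrx1a, and fli1a and foxf2a rose; the last 4 falls and both rises lie outside the rule for named genes and were added after their values were seen. The transcription factor gene twist1a, required for ectomesenchyme, fell from 847 and 1005 TPM to 498 and 469 TPM (log2 fold change -0.93 ± 0.11, adjusted p = 0.0028). The homeobox genes dlx4b and dlx3b fell by 2.59 ± 0.38 and 2.12 ± 0.30 (adjusted p = 0.0069 and 0.0075), and dlx2a fell by 0.63 from 598 and 662 TPM to 355 and 464 TPM. The rises were 0.89 for fli1a and 1.62 for foxf2a. Adjusted over the list alone, 3 rose and 11 fell. The median log2 fold change was -0.48 (-0.32 relative to all genes), both mutant samples lay below both wild-type samples for 18 of the 32 genes, against 34.9% of all tested genes, and the list as a whole did not pass (adjusted p = 0.055; 0.72 with an estimated correlation). It passed without mutant replicate 2 (adjusted p = 0.0016), without wild-type replicate 1 (0.0056), at a mean of 5 TPM or more (0.033), with quantile normalization (0.014) and with the replicate block (0.021). The medians of skeletal muscle and myeloid markers also lay lower in mutant cells, at -2.48 and -2.10. Without mutant replicate 1 the falls of dlx4b, tbx2b, foxc1b, dlx2a and prrx1a and the rise of foxf2a were not called (adjusted p = 0.07 to 0.19), nor without mutant replicate 2 were all of these or twist1a and fli1a (0.057 to 0.28). Without wild-type replicate 2 this held for foxc1b, dlx2a, prrx1a, fli1a and foxf2a (0.054 to 0.11), and without wild-type replicate 1 for fli1a (0.052). Under median-ratio scaling dlx3b, foxc1b, dlx2a and prrx1a did not pass (0.058 to 0.21), nor did prrx1a with quantile normalization (0.077) or foxf2a with the replicate block (0.057).

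Early neural crest genes moved both ways. The crest-specific transcript crestin rose from 187 and 145 TPM to 305 and 314 TPM (log2 fold change 0.91 ± 0.14, adjusted p = 0.0088), inka1a rose by 0.70 ± 0.13 (adjusted p = 0.017) and the crest specifier foxd3 rose by 0.65 ± 0.13 (adjusted p = 0.028). The gene snai2 fell from 188 and 178 TPM to 90.5 and 96.8 TPM (log2 fold change -0.96 ± 0.13, adjusted p = 0.0049), and sox9a also fell. Of 17 genes, 3 rose, 2 fell and 12 did not pass; adjusted over the list alone, 5 rose and 3 fell. The gene of the sorting reporter, sox10, did not pass (log2 fold change 0.53 ± 0.16, adjusted p = 0.10; chosen after its values were seen). The median of the list was 0.33 (0.50 relative to all genes), and the list rose as a set (camera, adjusted p = 0.046; adjusted p = 0.72 with an estimated correlation). The median was 0.13 without mutant replicate 1, 0.12 without wild-type replicate 2 and at most 0.45 without another sample. In the same samples the medians of skeletal muscle (-2.48), myeloid (-2.10), epidermis (-1.13) and endothelial (-0.82) markers lay the other way. The call of the list was lost under 9 of 18 alternatives: with no filter (adjusted p = 0.11), at a mean of 5 TPM or more (0.087), with quantile normalization (0.14), per transcript (0.071), per gene ID (0.069), without mutant replicate 1 (0.083) or wild-type replicate 2 (0.098), with the estimated correlation and with fry (0.82). The genes crestin, inka1a and foxd3 were not called without mutant replicate 1 (adjusted p = 0.066, 0.13 and 0.17) or without mutant replicate 2 (0.11, 0.12 and 0.14). The gene foxd3 was also not called without wild-type replicate 2 (0.059), nor snai2 without mutant replicate 2 (0.052), nor sox9a without any 1 of the samples (0.057 to 0.23) or with quantile normalization (0.052).

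**Figure D2:**
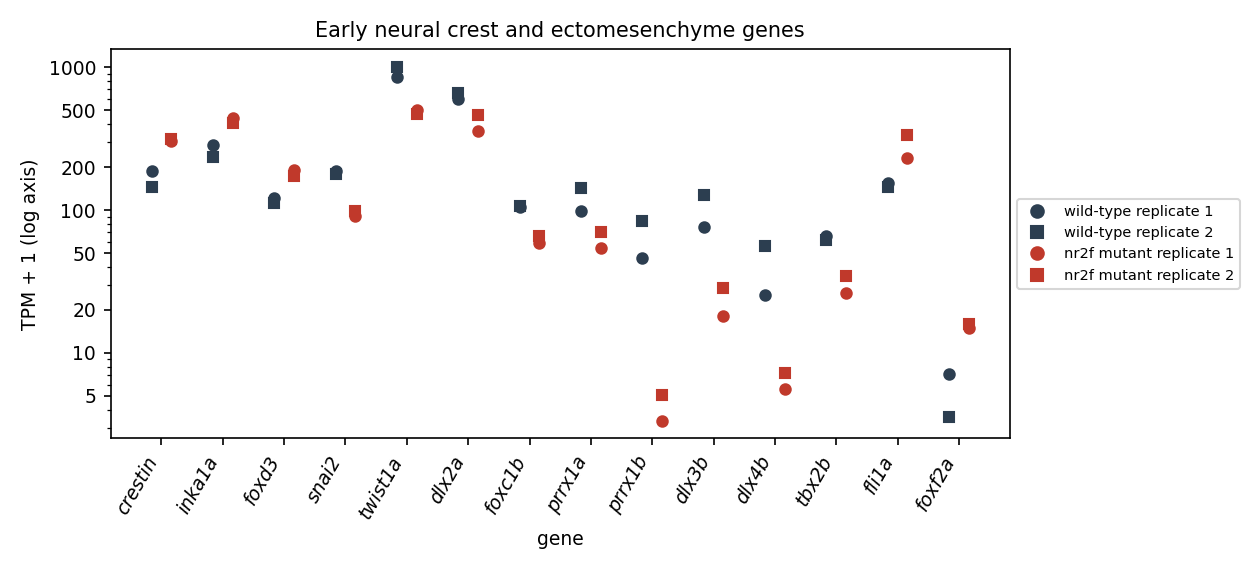
Abundance of early neural crest and ectomesenchyme genes in each sample, as TPM + 1 on a log axis, with wild-type samples in dark blue and nr2f mutant samples in red (circles, replicate 1; squares, replicate 2). The genes crestin, inka1a, foxd3, fli1a and foxf2a lie higher in both mutant samples, and snai2, twist1a, dlx2a, foxc1b, prrx1a, prrx1b, dlx3b, dlx4b and tbx2b lie lower.

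Within the arches, genes of the ventral and dorsal programmes were mostly not called. Falls were 3 of 14 ventral and 1 of 11 dorsal genes, against 419 of 14217 tested genes. These are too few to show an enrichment, and dlx4b, dlx3b and prrx1b are also among the ectomesenchyme falls. Of 14 ventral genes, dlx4b, dlx3b and the endothelin receptor gene ednraa fell (3 fell, 0 rose), and adjusted over the list alone 3 fell and 1, ednrab, rose. The ednraa values were 1.41 and 3.56 TPM in mutant and 15.9 and 9.76 TPM in wild-type cells, and the call was lost without mutant replicate 1 (adjusted p = 0.13), mutant replicate 2 (0.063) or wild-type replicate 1 (0.079) and with the replicate block (0.057). Of 11 dorsal genes, prrx1b fell; adjusted over the list alone, prrx1b, notch3 and jag1b fell and her9 rose. Neither list stood apart (adjusted p = 0.79 for ventral and 0.23 for dorsal genes), although the dorsal list passed without mutant replicate 2 (0.046). The lists share members, with 10 of the 14 ventral and 8 of the 11 dorsal genes also in other lists.

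Matrix genes fell as a set. Of 19 mesenchyme and matrix genes, 4 fell and 0 rose, and 13 fell adjusted over the list alone; both mutant samples lay below both wild-type samples for 14, against 34.9% of all tested genes. The collagen gene col1a2 fell from 37.0 and 27.2 TPM to 8.88 and 5.57 TPM (log2 fold change -2.02 ± 0.30, adjusted p = 0.0071), fn1b (a fibronectin) by 1.92, tnc by 1.43 and col5a2a by 1.57. The median was -0.87 (-1.32 to -0.75 when 1 sample was left out), or -0.71 relative to all genes (camera, adjusted p = 1.2e-04; adjusted p = 0.72 with an estimated correlation). Of 21 cartilage and bone genes, col1a1b, col1a2, hapln1b and sox9a fell and 0 rose, the same counts as adjusted over the list alone, and the list did not pass (adjusted p = 0.41; 0.0018 without mutant replicate 2). Endothelial markers fell as a set beside them, with a median of -0.82 (-0.43 without wild-type replicate 1, -1.34 without wild-type replicate 2), or -0.66 relative to all genes (camera, adjusted p = 0.0011; adjusted p = 0.72 with an estimated correlation). In that list stab2 fell by 2.55 and fli1b by 1.31, 2 of 22 genes over all genes and 3 adjusted over the list alone, and the call of the list was lost under 4 of 18 alternatives: without wild-type replicate 1 (adjusted p = 0.087), at a mean of 5 TPM or more (0.087), with the estimated correlation and with fry (0.25). The calls of fn1b, tnc, col5a2a, hapln1b and sox9a were lost without mutant replicate 1 (adjusted p = 0.091 to 0.14), mutant replicate 2 (0.14 to 0.28) or wild-type replicate 1 (0.08 to 0.17). That of sox9a was also lost without wild-type replicate 2 (0.057), and those of col1a2 and col1a1b without mutant replicate 2 alone (0.069 and 0.058). The call of stab2 was lost without mutant replicate 1 (0.067) or 2 (0.083), and that of fli1b without any 1 of the samples (0.079 to 0.23). Those of col5a2a and fli1b were also lost with quantile normalization (0.086 and 0.080) and with the replicate block (0.051 and 0.054), and that of sox9a with the former (0.052).

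Markers of skeletal muscle and of myeloid cells fell as sets, with the lowest medians of the called lists. Without wild-type replicate 1, however, the epidermis median (-2.69) lay below the myeloid median (-2.33). Of 24 muscle genes, smyhc1, unc45b, desma, srl and cav3 (the last chosen after its values were seen) fell and 0 rose; 10 fell adjusted over the list alone. The median was -2.48 (-3.17 to -1.78 when 1 sample was left out), or -2.32 relative to all genes (camera, adjusted p = 3.4e-14; adjusted p = 0.72 with an estimated correlation), and both mutant samples lay below both wild-type samples for 22 genes, against 34.9% of all tested genes. The abundant muscle actin gene actc1b, chosen after its values were seen, stood at 150 and 71.1 TPM in mutant and 411 and 1445 TPM in wild-type cells and did not pass (adjusted p = 0.32). Of 18 myeloid genes, 10 fell and 1, ctsc (chosen after its values were seen), rose; adjusted over the list alone, 13 fell and 2 rose. Among them the NADPH oxidase subunit gene ncf1 fell from 27.9 and 38.3 TPM to 2.62 and 2.51 TPM (log2 fold change -3.24 ± 0.30, adjusted p = 8.4e-04) and the myeloid regulator spi1b from 41.1 and 43.9 TPM to 6.08 and 5.59 TPM (log2 fold change -2.67 ± 0.25, adjusted p = 8.9e-04). The median was -2.10, or -1.93 relative to all genes (camera, adjusted p = 2.7e-06; adjusted p = 0.72 with an estimated correlation). The calls of unc45b, desma and cebpa were lost without mutant replicate 2 (adjusted p = 0.065, 0.065 and 0.053), those of srl and cav3 without mutant replicate 1 (0.10 and 0.13), mutant replicate 2 (0.17 and 0.24) or wild-type replicate 2 (0.089 and 0.15), and that of ctsc without mutant replicate 1 (0.13) or 2 (0.14). With quantile normalization srl and cav3 did not pass (0.059 and 0.097), nor did cav3 with the replicate block (0.062).

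Epidermis and periderm markers differed most between the wild-type replicates. In wild-type replicate 2 they lay higher than in replicate 1 by a median of 2.78 on the log2 scale, with krt4 (chosen after its values were seen) at 123 and 2040 TPM in wild-type replicates 1 and 2 and at 246 and 83.3 TPM in the mutant replicates. Of 27 genes, krt18a.1 fell by 1.13 ± 0.14 (adjusted p = 0.0032) and cdh1, the gene of E-cadherin, by 1.59 (adjusted p = 0.045), and 0 rose; 3 fell adjusted over the list alone. Both mutant samples lay below both wild-type samples for only 7 of the 27, against 34.9% of all tested genes. The list fell as a set (median -1.13, or -0.97 relative to all genes; camera, adjusted p = 0.016; adjusted p = 0.76 with an estimated correlation), but without wild-type replicate 2 it was higher in mutant cells (adjusted p = 0.023), and the call was lost with no filter (0.077), per transcript (0.062) and with fry (0.53). The call of cdh1 was lost without mutant replicate 1 (adjusted p = 0.10), mutant replicate 2 (0.28) or wild-type replicate 2 (0.14), with quantile normalization (0.099) and with the replicate block (0.071). Hatching gland and yolk syncytial markers had a median of -1.29 (12 genes, 1 of which, apoeb, fell, against 3 adjusted over the list alone; adjusted p = 0.12), and passed without mutant replicate 2 (0.024), without wild-type replicate 1 (1.2e-05) and at a mean of 5 TPM or more (0.044). Without wild-type replicate 2 the median was only -0.09 (adjusted p = 0.87). The gene apoeb was not called without mutant replicate 1 (0.07) or 2 (0.065).

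**Figure D3:**
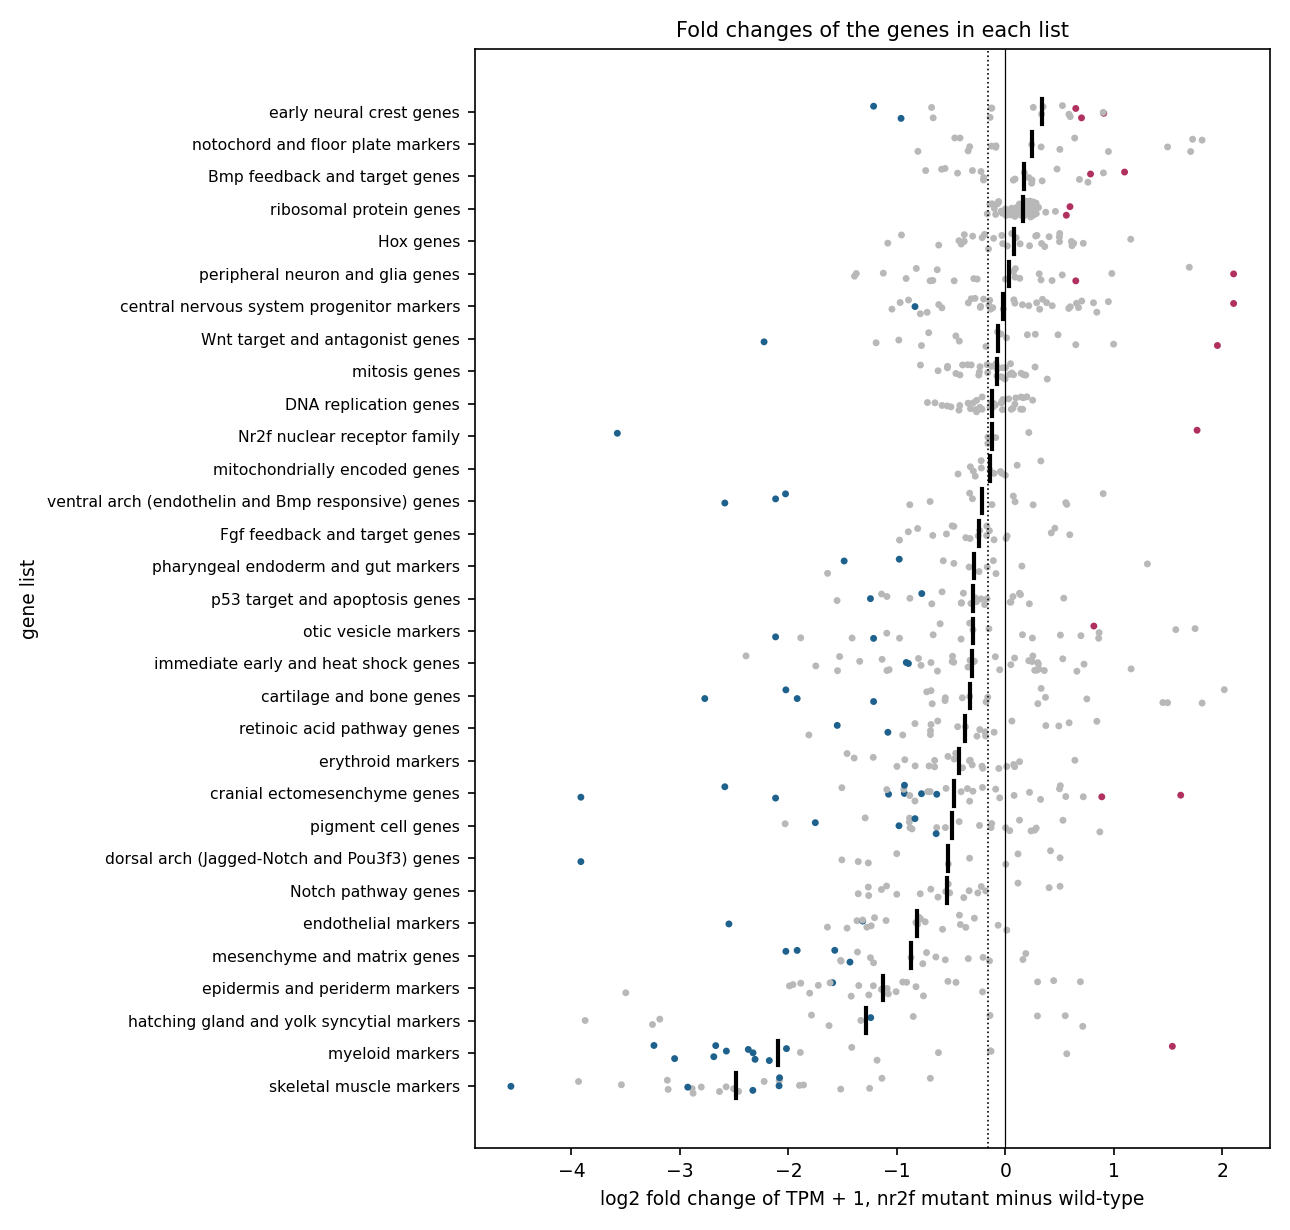
Log2 fold changes (TPM + 1, nr2f mutant minus wild-type) of the tested genes in each list, ordered by median. Points are genes (red, rose; blue, fell; grey, did not pass), black bars are list medians, and the dotted line is the median of all tested genes at -0.16; skeletal muscle and myeloid markers lie lowest, with medians of -2.48 and -2.10.

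Among signalling genes, the Bmp target and feedback genes rose as a set (median 0.18, or 0.34 relative to all genes; camera, adjusted p = 0.038; adjusted p = 0.72 with an estimated correlation). Both mutant samples lay above both wild-type samples for only 5 of the 21 Bmp genes, against 18.2% of all tested genes. In limma 2 of the 21 had an unadjusted p under 0.05, against 2900 of 14217 tested genes. Of the called lists, 3 rose, this one included, and 5 fell, among them skeletal muscle (-2.48) and myeloid (-2.10) markers. The median of the Bmp list was 0.06 without wild-type replicate 2, 0.09 without mutant replicate 2 and at most 0.20 without another sample. In that list id3, a direct Bmp target, rose from 147 and 140 TPM to 268 and 229 TPM (log2 fold change 0.79 ± 0.13, adjusted p = 0.012) and bambia rose by 1.1 ± 0.26 (adjusted p = 0.046), 2 of 21 genes, also adjusted over the list alone. The call of the list was lost under 8 of 18 alternatives: at a mean of 5 TPM or more (adjusted p = 0.053), under median-ratio scaling (0.066), per transcript (0.062), per gene ID (0.067), without mutant replicate 2 (0.058) or wild-type replicate 1 (0.17), with the estimated correlation and with fry (0.21). The call of id3 was lost without mutant replicate 1 (0.11) or 2 (0.063), and that of bambia without mutant replicate 1 (0.075), mutant replicate 2 (0.36) or wild-type replicate 1 (0.11). Retinoic acid pathway genes had 2 falls in 21, the retinoid binding protein gene rbp5 (log2 fold change -1.55 ± 0.24, adjusted p = 0.008) and the receptor gene rarga (-1.08 ± 0.18, adjusted p = 0.012), both not called without mutant replicate 1 (0.052 and 0.078); 4 fell adjusted over the list alone, and the list did not pass (adjusted p = 0.14). Of 17 Wnt genes, the antagonist gene sfrp5 fell by 2.22 and cdx4 rose by 1.96 (1 rose and 2 fell adjusted over the list alone; list adjusted p = 0.83); sfrp5 was not called without mutant replicate 2 (0.056) nor cdx4 without mutant replicate 1 (0.11). Of 20 Notch and 20 Fgf genes 0 passed in limma, with 5 genes of each at an unadjusted p under 0.05. Adjusted over the list alone, 1 Notch gene rose and 2 fell, and 0 Fgf genes passed. Neither list passed (adjusted p = 0.08 and 0.72), although the Notch list did without mutant replicate 2 (8.6e-04) and with the replicate block (0.034). The abundant Fgf genes spry2 and etv5b stood at 0.42 ± 0.14 and -0.47 ± 0.17.

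Most listed genes of crest derivatives other than ectomesenchyme did not pass. Over all 14217 tested genes, 419 fell and 161 rose, and 2900 had an unadjusted p under 0.05 in limma. Falls made up a larger share of the pigment list than of all genes, and rises a larger share of the neuron and glia list. These shares rest on only 4 and 2 genes of 24. Of 24 pigment cell genes, 4 fell and 0 rose: pnp4a, an iridophore gene, by 1.75 ± 0.31 (adjusted p = 0.017), aox5 by 0.98, pts by 0.64 and pax7a by 0.83, the last 3 tied to xanthophores. The melanocyte regulator mitfa, chosen after its values were seen, stood at 0.13 (adjusted p = 0.66). Adjusted over the list alone 6 fell, and the list did not pass (adjusted p = 0.13; 0.0088 without mutant replicate 2). The falls of pnp4a, pts and pax7a did not pass under median-ratio scaling (adjusted p = 0.081, 0.22 and 0.058) or with quantile normalization (0.064, 0.066 and 0.054), and all 4 were lost without mutant replicate 1 (0.087 to 0.23). That of pts was also lost without mutant replicate 2 (0.059), wild-type replicate 1 (0.074) or wild-type replicate 2 (0.11), and that of pax7a without mutant replicate 2 (0.30) or wild-type replicate 1 (0.21). Of 24 peripheral neuron and glia genes, egr2b and foxd3 rose and 0 fell (3 rose and 1 fell adjusted over the list alone; list adjusted p = 0.38). Of 32 Hox genes 0 passed in limma, over all genes or adjusted over the list alone, with 3 at an unadjusted p under 0.05; the abundant hoxa4a and hoxb3a stood at -0.38 ± 0.17 and 0.40 ± 0.23. The list had a median of 0.08, which was -0.17 without mutant replicate 1, 0.36 without mutant replicate 2, 0.25 under median-ratio scaling and 0.33 with quantile normalization. It did not pass (adjusted p = 0.052) but passed without mutant replicate 2 (3.0e-04), without wild-type replicate 1 (0.019), with no filter (0.027), at a mean of 5 TPM or more (0.038), with quantile normalization (0.016) and with the replicate block (0.032).

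Few genes of growth and stress passed singly. An unadjusted p under 0.05 in limma was reached by 2900 of 14217 tested genes, the share to set beside the counts below. Ribosomal protein genes rose as a set by a small amount, with a median of 0.17 (0.08 without wild-type replicate 1, 0.25 without wild-type replicate 2), or 0.33 relative to all genes (camera, adjusted p = 9.3e-15; adjusted p = 0.72 with an estimated correlation). Both mutant samples lay above both wild-type samples for 53 of 80 genes, against 18.2% of all tested genes. Skeletal muscle (-2.48), myeloid (-2.10) and endothelial (-0.82) markers lay lower in the same samples, among 5 called lists that fell and 3 that rose. Of the 80, rps4x rose by 0.60 ± 0.08 and rps13 by 0.56 ± 0.09 (adjusted p = 0.0042 and 0.01), 0 fell, and the same 2 passed adjusted over the list alone; both were lost without mutant replicate 1 (0.052 and 0.058) or 2 (0.11 and 0.19). The median was 0.35 under median-ratio scaling and 0.08 with quantile normalization, where the medians of all genes were 0.00 and 0.03. Ribosomal protein genes held 13.2% and 13.8% of TPM in the mutant replicates and 11.3% and 12.9% in the wild-type replicates. Of 37 DNA replication and 33 mitosis genes 0 passed in limma (7 and 3 at an unadjusted p under 0.05), and adjusted over the list alone 5 replication genes fell and 0 mitosis genes passed, among the former mcm7 (-0.34 ± 0.09) and mcm3 (-0.50 ± 0.13). The lists had adjusted p = 0.32 (0.0071 with quantile normalization) and 0.93, and the mitosis genes plk1 and ube2c stood at -0.02 and 0.08. Of 24 p53 target and apoptosis genes, casp3a fell by 1.24 and phlda3 by 0.77, and 4 fell adjusted over the list alone, with 6 at an unadjusted p under 0.05 (list adjusted p = 0.16; 0.032 without wild-type replicate 1). Of 38 immediate early and heat shock genes, mych fell by 0.91 and hspb1 by 0.89, and 6 fell adjusted over the list alone, with 15 at an unadjusted p under 0.05 (list adjusted p = 0.41). Of the 13 mitochondrially encoded genes 0 passed in limma, also adjusted over the list alone (2 at an unadjusted p under 0.05), and the list did not pass (adjusted p = 0.61; 0.038 without wild-type replicate 1), with mt-co2 at -0.32 and mt-co3 at -0.28. The calls of casp3a, mych, hspb1 and phlda3 were lost without mutant replicate 1 (0.058 to 0.16) or 2 (0.11 to 0.22), that of casp3a also without wild-type replicate 1 (0.068) and that of phlda3 without wild-type replicate 2 (0.14). Under median-ratio scaling hspb1 and phlda3 did not pass (0.081 and 0.13), nor did phlda3 with quantile normalization (0.055).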

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

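The alternatives were planned before the data were examined, except summing per gene ID, which was added after the data were seen. The fall of nr2f5 kept its direction under the 15 alternatives run for it (log2 fold change -3.60 to -3.40) and passed in all but limma without trend and robust, where the change was -3.58 with an adjusted p of 0.0631. That setting called 0 genes, 0 higher and 0 lower (2531 at an unadjusted p under 0.05). It also called 0 genes in the simulations that contained changed genes, where genes varied independently. Those simulations took their spreads from the fit with trend and robust. They therefore cannot tell whether the 0 calls in the data reflect low power or calls made in error in the main fit. No filter on low values gave 4 calls, 1 higher and 3 lower, among 22610 genes tested. Median-ratio scaling gave 364 genes higher, quantile normalization 254 lower, summing per gene ID 289 higher, and a log2 fold change of 1 or more 99 higher; the minimum removes calls by its construction, and for the others the cause was not tested. The count of calls ranged from 110 to 720 when 1 sample was left out, with 28 to 182 higher and 82 to 538 lower. Without mutant replicate 1 or 2, 195 and 110 genes were called. Fits without a wild-type replicate rest on as many samples yet called more than the 580. The number of samples alone therefore does not account for the lower counts. Fits without a mutant replicate take their spread from the wild-type pair. That pair differed more across genes (SD of log2 differences 0.62, against 0.52 for the mutant pair). A call lost in those fits therefore need not depend on the mutant sample left out. The number of gene lists past the threshold ranged from 8 to 16 when 1 sample was left out, was 5 per transcript, and was 0 with an estimated correlation and 0 with fry; the cause was not tested. Over their alternatives, the lists of skeletal muscle, myeloid, matrix and ribosomal protein genes lost their calls only with those last 2 tests. The epidermis list, with adjusted p from 6.5e-21 to 0.0365 when another sample was left out, reversed without wild-type replicate 2 (0.0229, higher in the mutant), the sample in which these markers were highest. The replicate numbers were checked for pairing: the differences between replicates 1 and 2 of the groups had a correlation of -0.012 across genes. This gave no sign of pairing but cannot exclude a shared clutch or day, which the replicate numbers do not state. With the replicate block 565 genes were called, 166 higher and 399 lower, of which 471 were among the 580, and 11 lists passed. Of 67 called named genes, 0 reversed under any alternative, 45 kept their call under each alternative that used a filter and a trend and left out no sample, and 21 also when any 1 sample was left out; 2 passed with no filter. The depth behind the TPM values is unknown, so the counting error of low genes could not be set.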

Other observations

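The tests of other cell types alike, of the eif3ea and eif3eb pair and of the other splits of the samples, the rates of falls and rises per tested gene and the medians by abundance, and the genes set beside their relatives (tyrosine breakdown, succinate dehydrogenase, ferritin-like genes and siblings named a and b), were chosen after the results were seen. The remaining tests were fixed before their results were seen, except that the error was added to the rule for myf5 and myod1 afterwards. Markers of some other tissues did not differ as lists. Beside the counts below, 2900 of 14217 tested genes had an unadjusted p under 0.05 in limma. Of 37 central nervous system progenitor genes, egr2b rose and pax7a fell, also adjusted over the list alone, and the median was -0.02 (-0.30 to 0.24 when 1 sample was left out) with a mean of 0.04 and a camera direction upward (adjusted p = 0.11; 1.9e-04 without mutant replicate 2 and 0.042 without wild-type replicate 1). Of 17 notochord and floor plate genes 0 passed in limma, also adjusted over the list alone (1 at an unadjusted p under 0.05; median 0.24, but -0.03 without mutant replicate 2, -0.04 without wild-type replicate 2 and 0.50 without wild-type replicate 1; list adjusted p = 0.077; 0.0031 without mutant replicate 1, 0.0088 without wild-type replicate 1 and 0.037 with quantile normalization), with col2a1a at 6.15 and 42.0 TPM in the mutant replicates. Of 24 erythroid genes 0 passed in limma, also adjusted over the list alone (11 at an unadjusted p under 0.05; median -0.43, and -0.68 to -0.21 when 1 sample was left out; list adjusted p = 0.066; 2.2e-04 without mutant replicate 2, 0.0044 without wild-type replicate 2 and 0.030 with quantile normalization). Of 21 otic vesicle genes, 11 of which are in other lists, msx3 rose and dlx3b and sox9a fell (2 rose and 5 fell adjusted over the list alone; list adjusted p = 0.93, and 0.0057 when genes shared with other lists were left out). Of 12 endoderm and gut genes, gsta.1 fell by 0.98 ± 0.12 (adjusted p = 0.0035) and hhex by 1.49 ± 0.32 (adjusted p = 0.033), and 1 rose and 3 fell adjusted over the list alone (list adjusted p = 0.41). The calls of msx3 and hhex were lost without mutant replicate 1 (0.22 and 0.079), mutant replicate 2 (0.065 and 0.23) or wild-type replicate 2 (0.081 and 0.083), and that of hhex with quantile normalization (0.061) and with the replicate block (0.051).

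Some related genes moved apart. Of the enzymes of tyrosine breakdown, hpdb and fah fell, whereas tat, hgd and gstz1 did not pass (log2 fold changes 1.15, -0.24 and -0.04; adjusted p = 0.14 for tat). The succinate dehydrogenase gene sdhda rose while its paralog sdhdb stood at 0.02 ± 0.17. Ferritin-like genes of 1 family went both ways: fthl27 fell from 866 and 834 TPM to 535 and 548 TPM, fthl28 rose from 15.6 and 30.5 TPM to 68.0 and 89.3 TPM, and fthl30 rose as well, whereas fthl29 and fthl31 did not pass (0.14 and 0.44; adjusted p = 0.83 and 0.16); reads shared among such copies make these values uncertain, and all 3 calls were lost without mutant replicate 1 (adjusted p = 0.058 to 0.12) or 2 (0.092 to 0.22). Under median-ratio scaling fthl27 and fthl28 did not pass (0.13 and 0.051), nor did fthl28 with quantile normalization (0.060). Among called genes named with the suffix a or b, 130 had their sibling tested, and the sibling was called the same way for 20 and the opposite way for 8: eif3ea and eif3eb, fli1a and fli1b, gna13a and gna13b, and npm1a and npm1b. Only the eif3e pair kept both calls when any 1 sample was left out. The call of gna13a was lost without mutant replicate 1 (adjusted p = 0.17), that of gna13b without mutant replicate 2 (0.16) or wild-type replicate 1 (0.062), and that of npm1a without mutant replicate 1 (0.19) or 2 (0.23), under median-ratio scaling (0.060) and with quantile normalization (0.10). The call of fli1a was lost without mutant replicate 2 (0.19), wild-type replicate 1 (0.052) or 2 (0.067), and that of fli1b without any 1 of the samples (0.079 to 0.23).

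More genes fell than rose in mutant cells, 419 against 161. The share went with abundance: falls made up 84.8% of the calls at 1 to 5 TPM, 76.9% at 5 to 50 TPM and 52.6% at 50 TPM or more (95% exact interval 44.4 to 60.6), and median-ratio scaling gave 364 rises. Called falls were no more frequent among low genes, at 2.44%, 3.41% and 2.77% of tested genes in these ranges. Called rises climbed from 0.437% to 1.02% and 2.5%. Because log2(TPM + 1) understates the changes of low genes, these rates neither show nor exclude that falls were more frequent there. The understatement applies to rises and falls alike, so it does not account for their balance. There were 117 falls and 21 rises at 1 to 5 TPM, and 82 and 74 at 50 TPM or more. The median log2 fold changes of all tested genes were -0.35, -0.19 and 0.05. The share of falls met the rule fixed beforehand for a lower complexity of the mutant libraries. Falls were not shown to be more frequent among low genes than among abundant ones. A lower complexity of the mutant libraries, which had more tested genes listed at 0 (81 and 243 against 60 and 39), is a candidate explanation of the shift with abundance. RNA from fewer other cells in the mutant sorts would also lower many low genes and was not separated from this, and an effect of the genotype on low genes stays open as untested.

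Skeletal muscle markers had a median log2 fold change of -2.48 in the mutant samples, although the sort for sox10:DsRed should leave muscle out. A lower share of all other cell types alike is argued against by erythroid markers. Their medians, in full and when 1 sample was left out, were -0.68 to -0.21, against -3.17 to -1.78 for muscle. The 7 abundant globin genes stood at -0.70 to -0.31. Myeloid (-2.10), hatching gland (-1.29), epidermis (-1.13) and endothelial (-0.82) medians also lay lower. Such medians lay above those of muscle for 7 of the 9 other lists. That count says less, because some lists share genes with crest or cartilage lists and the changes of low genes are understated. A share of muscle RNA that varies between sorts of 1 genotype is a candidate explanation, since wild-type replicate 2 lay above wild-type replicate 1 by a median of 1.29, for 22 of 24 genes, with actc1b at 1445 and 411 TPM. Slower development of mutant embryos would leave the early genes myf5 and myod1 less lowered. They stood on either side of the limit of -1, at -0.69 ± 0.46 and -1.90 ± 0.56. Their mean of -1.29 ± 0.36 was below -1, which by the rule fixed beforehand counted against slower development. With the error added to the rule afterwards, the mean lay too near the limit to decide. A lower share of several other cell types together, and an effect of the genotype on muscle or on reporter expression in it, stay open as untested.

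Some single genes changed by large amounts, with eif3eb (-3.73) among the 10 largest falls. For eif3eb the fall lay in 1 gene ID (380 and 353 TPM in wild-type cells, 0.949 and 0.232 TPM in mutant cells), and the summed TPM of eif3ea and eif3eb was 880 and 907 in mutant and 779 and 761 in wild-type cells, a log2 fold change of 0.21. This is consistent with reads of 1 gene being assigned to different sequences in the 2 groups, as a strain variant could bring about; it bears on this pair and no other. Variants close to the nr2f5 mutation, as the source of many calls of any size, are argued against. Of the 100 tested genes nearest nr2f5, 4% were called, below the 8% that marks the top 5% of such windows. Near nr2f2 5% were called, but that window tests linkage only if nr2f2 is mutated, and its genotype is unknown. Both windows count all calls, not only large changes. Single linked genes and large changes linked over a wider stretch stay open, as do the genotype itself and the genetic background of the mutant line. In the order of tested genes, hjv (-3.34), 1 of the 10 largest falls, lies 33 genes from nr2f5. Called genes nearer to it were rpz2 (1.32, at 2 genes), gapdhs (1.32, at 11) and sult2st3 (2.08, at 13). Nearest nr2f2 were fkbp16 (-2.82, at 8) and znf710a (-1.79, at 9). These genes except hjv were chosen after their values were seen. On the chromosome of nr2f5, 5.04% of the genes were called against 3.99% of all matched genes. With nr2f5 included, 19 of its 537 tested genes were called with a large change, by a fixed limit on the log2 scale. That was the highest share of any chromosome, seen afterwards, ahead of 14 of 442 and 22 of 700 genes on others. Its cause was not tested.

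With 4 samples there are 3 splits into 2 and 2, too few for a share under 0.05. The real split, 1 of the 3, called 580 genes, and the highest of the others called 0 in limma, with 165 and 116 genes at an unadjusted p under 0.05 in the others.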
